A study of Mus musculus with 14 samples.

How the data were processed

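Mouse embryonic stem cells with floxed Mll1 alleles and a tamoxifen-inducible Cre recombinase (C57BL/6J) were grown without feeders on Matrigel, in medium with LIF, 5% serum and 15% serum replacement. They were left untreated, grown with the MLL1 inhibitor MM-401 at 100 µM, or grown with 4-hydroxytamoxifen (4-OHT) at 5 µM to delete Mll1, for 9 days and 3 passages. Chromatin was fixed with 1% paraformaldehyde for 10 minutes and precipitated with 4 µg of antibody against Mll1 or 2 µg against H3K4me1, H3K4me2 or H3K4me3. The study holds 14 libraries: 10 precipitated libraries with a peak list each and 4 inputs, which enter only as the controls of the peak calls.

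The authors called peaks in each precipitated library alone against 1 input. Per the file headers this was done with MACS 1.4.2 on libraries with duplicate tags removed, with a p cutoff of 1e-05, an effective genome size of 2.7e+09, a band width of 300 bp and local background windows of 1000 and 10000 bp. The submitters' notes name Bowtie2, SAMtools 1.5, MACS2 and the genome build mm10, so the notes and the headers differ on the version of the caller; the headers were followed. The deposited counts are numbers of tags in a peak after removal of duplicates, not scaled to depth. The deposited score is the negative log10 of the MACS p of the peak times 10; the lowest value was 50 and values were capped near 3100. The deposited ratio is the fold enrichment of the peak summit over the local background, and it was not used for any comparison. The deposited percent is the false discovery rate that MACS obtains by swapping precipitated library and input. One other deposited value is the width of the peak in bp, which equals end minus start plus 1. The score depends on depth, so it was used only to rank peaks within a list. Per the file headers, the untreated, 4-OHT and Mll1 libraries were processed in one folder and the MM-401 libraries in another, so batch and MM-401 cannot be told apart.

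Tags left after removal of duplicates ranged from 12.9 M (MM-401, H3K4me3) to 61.8 M (4-OHT, H3K4me1), with M for 1000000 tags. The MM-401 libraries held 60.3%, 49.5% and 51.2% of the untreated tags for H3K4me1, H3K4me2 and H3K4me3, and the 4-OHT libraries held 167%, 121% and 105%. Each group is 1 library, so no test across libraries was possible and no p-values were computed. Intervals are exact: Clopper-Pearson for shares of peaks and Poisson for tags at a gene, both at 95%. They cover counting error only.

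Peaks on the 19 autosomes and on X and Y were analysed. Genes were the 21887 protein-coding genes of GRCm38 (mm10). The plan had been to use annotated transcription start sites, exons and introns, but the annotation used here gave only the 2 ends of each gene without strand. A peak was therefore placed at a gene end when it came within 1 kb of either end, else in a gene body, else between genes. For 15408 genes the start was inferred as the end with more H3K4me3 cover. An untreated peak was lost when no treated peak of the same mark overlapped it by at least 1 bp, and a treated peak was gained when no untreated peak did. A gene lost a mark when a peak lay within 1 kb of one of its ends in untreated cells and none did in treated cells. Peaks overlapping an Mll1 peak were set against other peaks of the same untreated list in 10 classes of score and 5 classes of width. Genes and peaks lost under both treatments were set against losses independent within the same classes; for genes this was added after the data were examined. Positions were compared with 100 lists shuffled within chromosomes.

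For genes with a peak at the inferred start in all 3 conditions of a mark, the covered length within 5 kb of the start was compared as a log2 ratio of treated to untreated. The width of the peak at the start, the tags of peaks within 1 kb of it per M filtered tags, the summed width of those peaks and the tags per kb were compared in the same way. The tag measures were added after the data were examined. Because tags are summed over whole peaks, the value of a gene can move when a neighbouring peak comes into or leaves that 1 kb. A list of genes was set against 10000 random gene sets of the same size and of the same classes of untreated score and width. For widths after joining of peaks, the classes were 20 of joined untreated width alone. The central 95% of the random medians or counts is given (seed 7, with another seed for joined widths). Scores at the cap are tied, and 25.8% of untreated H3K4me3 and 15.5% of H3K4me2 peaks were there. Among such peaks, and genes with such peaks, matching was by width and not by strength. The 21 gene lists, with 310 of their 313 genes found, were chosen before the data were examined. H19, Kcnq1ot1 and Meg3 were not in the protein-coding set.

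All list genes could be named. Beyond them the rule named, for each mark and treatment, the 10 genes with the highest score among those losing and among those gaining a peak at a gene end, the 15 genes with the highest-scoring Mll1 peak, and for each mark the 10 highest-scoring genes losing it under both treatments. Ties went by width and then by name. Predicted genes with Gm or Rik names were counted and not named.

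The alternatives were overlap of 50% of the peak, a distance of up to 1 kb in place of overlap, the upper 50% of each list by score, lists of equal number, peaks under 1 kb apart merged, no matching of peaks or of random genes, gene ends alone or peaks away from them, the inferred start alone, a 2.5 kb window and the nearest peak's width. The summed width, Mll1 peaks with a false discovery rate of at most 5%, and genes at which the peak itself had no overlapping peak were added after the data were examined. The code was tested on simulated data. A lost share of 10.3% was recovered as 10.3%, and a gained share of 5.95% as 5.95%. An added loss of 15 percentage points at Mll1-overlapping peaks was recovered as 16.0, and no added loss as 0.53. Of 200 simulated lists without an effect on the count of lost genes, 2.5% fell outside the central 95%. More genes were lost in that simulation than in the real comparisons, so it does not cover counts as low as those found here. Of 200 lists with a median raised by 0.4, 97.5% lay above the central 95%. Medians without an effect were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.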

Results

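The data are lists of enriched regions (peaks) from chromatin immunoprecipitation and sequencing of mouse embryonic stem cells, with 1 library per group and no replicates. Mll1, a methyltransferase of histone H3 lysine 4 (H3K4) also called Kmt2a, was mapped in untreated cells. The mono-, di- and trimethylated forms of this lysine (H3K4me1, H3K4me2 and H3K4me3) were mapped in untreated cells, in cells grown with the inhibitor MM-401 and in cells given 4-OHT to delete Mll1. H3K4me3 is typical of gene starts and H3K4me1 of enhancers and of the flanks of starts. Positions are on GRCm38 (mm10), tags are counted in M (1000000 tags), and all intervals are 95% and cover counting error only.

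The Mll1 library held 30.1 M filtered tags and gave 4004 nuclear peaks with a median width of 164 bp and a median of 11 tags. Only 0.285% of its tags lay in these peaks. The fragment size modelled by the caller was 53 bp for tags of 51 bp, against 179 to 293 bp in the mark libraries. Enrichment was thus weak, and every comparison that uses Mll1 peaks carries that limit. Untreated H3K4me1, H3K4me2 and H3K4me3 held 36.9, 40.1 and 25.3 M tags and gave 119739, 89538 and 52912 peaks, with 63.7%, 71.3% and 82.5% of tags in peaks. MM-401 libraries held 22.2, 19.8 and 12.9 M tags and gave 82150, 60348 and 32191 peaks, with 58.5%, 72.4% and 85.6% of tags in peaks. The 4-OHT libraries held 61.8, 48.6 and 26.4 M tags and gave 119230, 98906 and 56419 peaks, with 67.3%, 77.8% and 87.5% of tags in peaks. In both treatments the inputs differed in depth as well, at 36.6 M filtered tags for untreated cells, 12.2 M for MM-401 and 55.0 M for 4-OHT.

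Kmt2a itself (chromosome 9, 44803355 to 44881352), the gene that 4-OHT was given to delete, was looked at first as a check of the labels. Its start carried H3K4me3 in all 3 conditions, at 107 tags per M (103 to 111) in untreated cells, 118 (112 to 124) after MM-401 and 107 (103 to 111) after 4-OHT, over peaks 5232, 5349 and 5271 bp wide. H3K4me2 stood at 50.6, 56.7 and 51.2 tags per M. H3K4me1 differed more, at 5.18 (4.47 to 5.97) tags per M in untreated cells, 19 (17.3 to 20.9) after MM-401 and 43.0 (41.4 to 44.7) after 4-OHT, as its peak went from 2349 to 5561 and 18188 bp. Methylation at the start of the gene does not test the deletion, because the part of Kmt2a that is removed was not stated in the sources used here.

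The untreated libraries show where Mll1 peaks were called, at the weak enrichment given above, and which marks lay with them. Mll1 peaks lay at the ends of 931 protein-coding genes, among them several transcription factors that hold embryonic stem cells pluripotent. Of the core pluripotency list, 4 of 14 genes had one (Nanog, Sall4, L1td1 and Dppa2), and of the naive pluripotency list 6 of 16 (Tbx3, Dppa3, Zfp42, Klf2, Dppa5a and Klf5). Over all genes the count was 931 of 21887, and the lists were not tested against it. The Hox clusters, which pattern the body axis and are classic targets of Mll1, had 3 of 39 (Hoxa2, Hoxa5 and Hoxc11), Wnt signalling had 2 of 14 (Sfrp1 and Ctnnb1), formative and primed pluripotency had 1 of 14 (Sox4), and primitive streak and mesoderm had 1 of 16 (Tbx6). Housekeeping genes had 2 of 16 (Gapdh and Tuba1b), and the other 14 lists had 0.

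Among the named genes with the highest Mll1 score were Elobl (peak on chromosome 11, 88967768 to 88969552, 367 tags), Hjurp, which loads the centromeric histone (chromosome 1, 88276179 to 88278582, 281 tags), Tmem267 (104 tags), the neighbours Abhd4 and Dad1 (chromosome 14, 54253740 to 54254069, 27 tags), the tubulin gene Tuba1b (chromosome 15, 98933782 to 98934062, 21 tags) and Hells, a chromatin remodeller needed for DNA methylation (chromosome 19, 38929220 to 38929530, 21 tags). Slc2a5, Steap1, Apoc1, Txndc15, Ubr3, Pigl, Alyref2 and Ddhd2 made up the rest. The false discovery rate given for the Elobl peak was 0%, but it was 33.3% for Hjurp, 18.8% for Tuba1b, 18.2% for Abhd4 and Dad1, 15.8% for Tmem267 and 12.9% for Hells. Of the whole list, 3754 peaks (93.8%) had a rate of at most 5%.

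Most Mll1 peaks lay on H3K4 methylation. H3K4me1 overlapped 2871 of them, or 71.7% (70.3 to 73.1), H3K4me2 overlapped 68.2% (66.8 to 69.7) and H3K4me3 overlapped 50.4% (48.8 to 52.0). Shuffled Mll1 peaks overlapped 13.0%, 8.63% and 4.15%, so the ratios were 5.53, 7.90 and 12.1. All 3 marks lay on 1826 Mll1 peaks, of which 36.6% were at gene ends, and 684 had H3K4me1 and H3K4me2 without H3K4me3, of which 4.39% were at gene ends. Another 907 (22.7%) had none of the marks, and 2.87% of those were at gene ends. In the other direction Mll1 covered few marked regions, overlapping 2.22% of H3K4me1, 2.81% of H3K4me2 and 3.56% of H3K4me3 peaks. Of all Mll1 peaks, 21.2% (19.9 to 22.5) were at gene ends against 3.50% of shuffled peaks, 42.1% were in gene bodies and 36.7% were between genes.

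**Figure D1:**
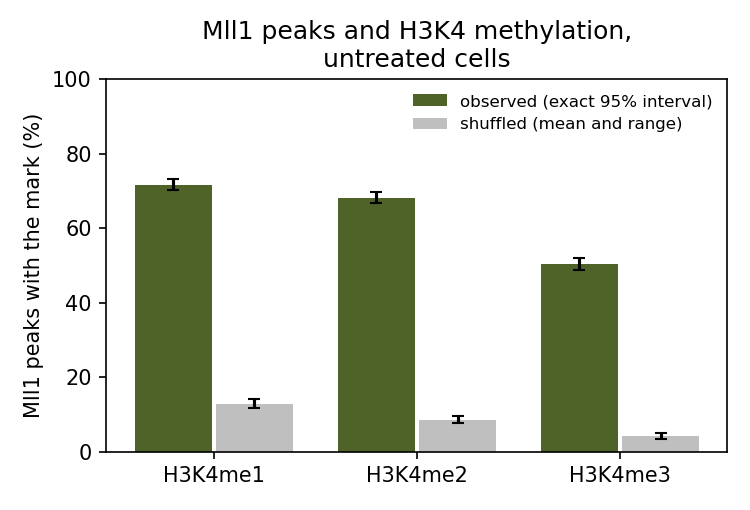
Share of untreated Mll1 peaks (vertical axis, percent) that overlapped a peak of each mark (horizontal axis), with exact 95% intervals, beside the mean and range of 100 shuffled lists in grey. The observed shares of 71.7%, 68.2% and 50.4% stand above shuffled shares of 13.0%, 8.63% and 4.15%.

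At gene ends, untreated H3K4me1, H3K4me2 and H3K4me3 had 21.6%, 20.1% and 29.2% of their peaks. The shares were 26.7%, 26.7% and 43.1% after MM-401 and 21.6%, 18.8% and 27.7% after 4-OHT. Among untreated H3K4me3 peaks, 97.6% overlapped H3K4me2 and 83.6% overlapped H3K4me1.

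The comparison of MM-401 with untreated cells asks which methylated regions depend on Mll1 activity. After MM-401, gene starts of the core pluripotency, Hox and neuroectoderm lists kept their H3K4me3 almost without exception. Germline and primitive endoderm genes had fewer H3K4me3 tags per M. Only 1 tag per position was kept, and the rate of redundant tags for H3K4me3 was 0.6 in untreated cells and 0.42 after MM-401. Whether their removal moved tags per M at strong or weak starts was not tested. Pou5f1, the Oct4 gene (chromosome 17, 35506032 to 35510777), stood at 166 (159 to 173) tags per M of H3K4me3 against 116 (112 to 120) in untreated cells, and Nanog (chromosome 6, 122707489 to 122714633) at 240 (231 to 248) against 172 (167 to 177). Sycp3, a part of the meiotic chromosome axis (chromosome 10, 88459587 to 88473236), stood at 8.90 (7.35 to 10.7) against 22.6 (20.8 to 24.6). Across the genome, weak regions away from gene ends, inside genes as well as between them, were the ones most often without a peak.

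For the germline list, H3K4me3 tags per M were lower in all 12 genes with a peak in every condition, with a median log2 ratio of -0.59, below the central 95% of random gene sets (-0.49 to 0.15). Covered regions were slightly narrower, with a summed width of -0.12, and tags per kb stood at -0.55. Sycp1 went from 19.9 (18.2 to 21.7) to 9.36 (7.77 to 11.2) tags per M, the X-linked Rhox13 from 13.6 (12.2 to 15.1) to 5.72 (4.50 to 7.19), and Taf7l, a testis form of a general transcription factor, from 11.5 (10.2 to 12.9) to 5.88 (4.63 to 7.36). Slc25a31 had 3.44 tags per M in untreated cells and no peak after MM-401. H3K4me2 of the germline list had a median of -0.29 (random sets -0.21 to 0.26), with 4 of 13 genes higher.

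Primitive endoderm genes, which mark the extra-embryonic lineage set aside next to the pluripotent cells, had a median H3K4me3 log2 ratio of -0.38 with 1 of 8 genes higher (random sets 0.02 to 0.34), at a summed width of -0.04 and tags per kb of -0.07. Gata6, a lineage-defining factor (chromosome 18, 11052510 to 11085636), stood at 60.9 (56.7 to 65.3) against 78.9 (75.5 to 82.5) tags per M, over peaks of nearly the same width. Col4a1 was the exception, at 61.0 against 56.8. H3K4me1 of the same list went the other way among genes with a peak in all 3 conditions, with a median of 0.30 and 7 of 8 higher. That was just above the random sets (-0.29 to 0.29). This leaves out Afp and Gata4, the 2 of 11 genes of the list that lost H3K4me1 after MM-401 (random mean 1.49). Retinoid and vitamin D signalling had a median of -0.36 (random sets -0.29 to 0.27), with 2 of 10 genes higher and tags per kb of -0.34. Cyp27b1, which activates vitamin D, went from 12.0 (10.7 to 13.5) to 5.96 (4.70 to 7.45), and Cyp26a1, which degrades retinoic acid, from 38.8 (36.4 to 41.3) to 27.1 (24.3 to 30.1) over a narrower peak (3160 against 4804 bp). Trophectoderm genes stood at -0.08 (random sets -0.05 to 0.30), and the placental regulator Hand1 went from 33.6 to 13.4 tags per M as its peak went from 7488 to 3567 bp. By cover within 5 kb, germline, primitive endoderm, retinoid and trophectoderm lists all lay inside the random sets, at -0.12, -0.02, 0.04 and 0.01, while primitive streak and mesoderm (-0.16, random sets -0.06 to 0.13) and the H3K4 methylation machinery (-0.16, -0.10 to 0.05) lay below them.

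Core pluripotency genes stood above the random sets by the tag sum alone, with a median H3K4me3 tag ratio of 0.37 and 12 of 14 genes higher (random sets 0.11 to 0.33). Their summed width stood at 0.01 and tags per kb at 0.36. By either of these measures 0 of 20 lists stood above their random sets. Cover within 5 kb, the measure chosen first, stood at -0.04, inside the random sets (-0.12 to 0.05). Among all 14476 genes compared, the median was 0.16. Utf1, a chromatin factor of undifferentiated cells, went from 81.4 to 138 tags per M. Otx2, an early marker of the step from naive to primed cells (chromosome 14, 48656781 to 48667644), went from 39.6 (37.2 to 42.1) to 90.7 (85.6 to 96.0), over a peak that went from 3715 to 10221 bp.

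Hox genes had higher H3K4me1 and H3K4me2 after MM-401 with little difference in H3K4me3. Their median log2 tag ratio was 0.34 for H3K4me1 with 33 of 39 genes higher (random sets -0.17 to 0.14), 0.39 for H3K4me2 with 38 of 39 higher (0.12 to 0.24), and 0.05 for H3K4me3 with 22 of 38 higher (-0.06 to 0.19). Covered width at these genes was almost the same, at -0.00 for H3K4me1 and 0.04 for H3K4me2, and tags per kb stood at 0.34 (random sets 0.13 to 0.27) and 0.33 (0.16 to 0.28). Over all genes the medians of tags per kb were 0.19 and 0.21. Hox genes lie in clusters where neighbours can share a peak, while random genes were drawn singly over the genome. The random ranges may thus be too narrow for the Hox list, and its genes do not count as separate. Hoxd9 went from 23.8 to 38.8 tags per M of H3K4me2 and Hoxc9 from 12.7 to 20.9. Neuroectoderm genes moved in the same direction in 14 of 14 genes for both marks, with medians of 0.36 for H3K4me1 (random sets -0.28 to 0.23) and 0.37 for H3K4me2 (0.08 to 0.26). Sox1, the earliest marker of neural precursors, had 81 tags per M of H3K4me2 over 10056 bp against 40.4 over 6005 bp, and Olig2 had 135 against 108.

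Of the 310 list genes, 286, 282 and 274 had H3K4me1, H3K4me2 and H3K4me3 at a gene end, and MM-401 left 12, 4 and 3 of them without it. H3K4me1 was absent at the endoderm genes Afp and Gata4, the germline genes Sycp1, Tex11 and Taf7l, the blood regulators Spi1 and Ikzf1, the blood and endothelial surface gene Cd34, the mesenchymal genes Dcn and Acta2, the imprinted Plagl1, and Hprt. H3K4me2 was absent at Esrrb, a naive pluripotency factor, at Dpy30, a subunit of H3K4 methyltransferase complexes, and at Acta2 and Pecam1. H3K4me3 was absent at Afp, Hoxb3 and Slc25a31. None of these list counts lay outside the random sets. The random sets reached down to 0 for each list, so fewer losses than in random genes could not show. The germline list lost H3K4me1 at 3 of 12 genes against a random mean of 1.72. With random genes not matched, blood and endothelium lay outside, with H3K4me1 lost at 3 genes against at most 2.

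Of all genes with the mark, MM-401 left 1107 of 16163 (6.85%) without H3K4me1, 626 of 16083 (3.89%) without H3K4me2 and 697 of 15225 (4.58%) without H3K4me3, while 121, 36 and 36 gained it. With lists of equal number 539, 246 and 227 lost it and 629, 139 and 161 gained it, so that for H3K4me1 gains outnumbered losses. The 10 highest-scoring genes named for H3K4me3 were Klb, Armt1, Ppp1r37, Ift46, Npr2, Lcat, Cln3, Nin, Tbc1d5 and Rinl, and at each of them an overlapping MM-401 peak still stood just outside the 1 kb. Genes whose untreated peak had no overlapping MM-401 peak numbered 996, 578 and 651. Those with the highest H3K4me3 scores, chosen after their values were seen, were Phkg1, a kinase of glycogen breakdown (chromosome 5, 129863909 to 129866802, 273 tags), Tmem233 (chromosome 5, 116081872 to 116083530, 166 tags) and the decoy receptor gene Il1r2 (chromosome 1, 40085207 to 40086608, 165 tags). For H3K4me1, Siglecf (chromosome 7, 43342691 to 43350403, 1166 tags), Saa2, Hsh2d, Aoc2, Rrbp1, Slc4a9, Gipc1 and Chadl were among those named, and 0 of the 10 lacked an overlapping peak. Slc7a7, Fnbp1, Ddc, Mmp19, Dcaf1, Prrxl1, Tmem140, Ccn6, Vsig10l and Tasor2 were named for H3K4me2, again with 0 lacking one. Genes gaining H3K4me1 included the growth factor gene Igf1, the retinoic acid receptor gene Rarb, Exoc6b, Cd101 and Kcnj1, at each of which an untreated peak already lay under the new one.

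As shares of peaks, MM-401 left 34.4% (34.2 to 34.7) of H3K4me1, 33.8% (33.5 to 34.1) of H3K4me2 and 38.2% (37.8 to 38.6) of H3K4me3 peaks without an overlapping peak, and 3.36% (3.24 to 3.49), 2.70% (2.57 to 2.83) and 0.864% (0.765 to 0.971) of MM-401 peaks were gained. Gene ends lost 14.4%, 9.79% and 9.47% of their peaks against 39.9%, 39.9% and 50.1% elsewhere. Lost H3K4me3 peaks had a median of 43 untreated tags and kept ones 266. With lists cut to the same number of peaks, the lost shares were 16.3%, 13.1% and 10.6% and the gained shares 13.4%, 12.8% and 11.2%. MM-401 libraries were shallower and came from another processing batch, so neither the lost peaks nor the level differences can be separated from the batch.

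**Figure D2:**
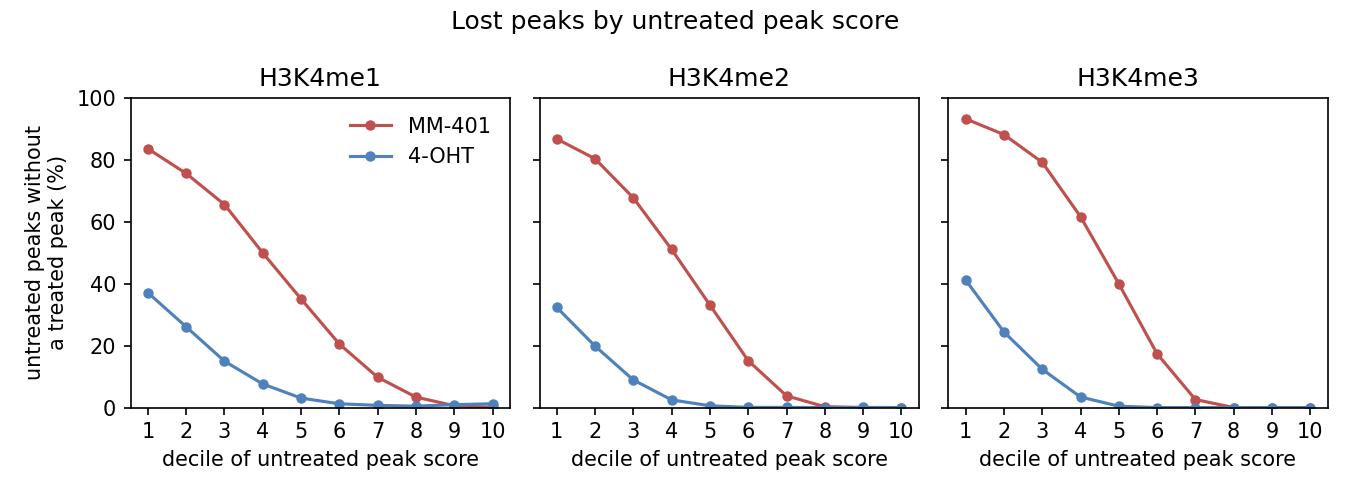
Share of untreated peaks without an overlapping treated peak (vertical axis, percent) in 10 classes of untreated score from lowest to highest (horizontal axis), with a panel for each mark, MM-401 in red and 4-OHT in blue. In the lowest class of H3K4me3, 93.3% were lost after MM-401 and 41.2% after 4-OHT, and in the 3 highest classes 0% were lost. Tied scores at the cap make the upper classes unequal: class 9 of H3K4me3 holds 13447 peaks and class 10 holds 182.

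The comparison of 4-OHT with untreated cells asks the same of cells given 4-OHT to delete Mll1. Mll1 was not mapped after 4-OHT, so the deletion itself was not measured. Summed over whole peaks, H3K4me3 tags were higher at every one of the 14 core pluripotency genes, where the peaks were also wider. A wider peak holds more tags, so this sum alone does not show a higher level per kb. By the same sum, neuroectoderm genes stayed inside the range of random genes and the Hox clusters lay slightly below it. L1td1 (chromosome 4, 98726754 to 98738486) stood at 170 (165 to 175) tags per M against 78.4 (75.0 to 82.0), Dppa2 at 72.1 (68.9 to 75.4) against 35.6 (33.3 to 38), Foxd3 (chromosome 4, 99656299 to 99658671) at 109 (105 to 113) against 52.6 (49.8 to 55.5), and Pou5f1 at 172 (167 to 178) against 116 (112 to 120). Sycp3 stood at 23.4 (21.6 to 25.3) against 22.6 (20.8 to 24.6). No list gene lost H3K4me3.

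The median core pluripotency log2 ratio of H3K4me3 tags was 0.59 (random sets -0.00 to 0.17), with a summed width of 0.48 and tags per kb of 0.12, and among all 14476 genes the tag median was 0.01. Peaks at these genes became long. Trim71, which regulates mRNAs of stem cells (chromosome 9, 114511268 to 114564369), had a peak of 42506 bp against 22753, Sall4 (chromosome 2, 168748332 to 168767201) one of 16106 against 9075, Nanog one of 15611 against 11320, and L1td1 one of 13003 against 6497. Sox2 (chromosome 3, 34649995 to 34652461) was almost the same, at 10758 against 10320. The median log2 ratio of the width of the peak was 0.48 with 14 of 14 genes wider (random sets 0.02 to 0.24), and after MM-401 it was 0.01 with 7 of 14 wider. Cover within 5 kb of the start, the measure chosen first, saturates at such widths and stood at 0.15 (random sets 0.01 to 0.18). With peaks under 1 kb apart joined in every library, the median width ratio was 0.26, inside the random sets (0.02 to 0.30). All 14 of 14 genes were still wider, and these random sets were matched on joined width alone.

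H3K4me2 followed at the core pluripotency genes, with a median tag ratio of 0.38 (random sets 0.00 to 0.23), a summed width of 0.37 and 14 of 14 genes higher. Sox2 went from 108 (104 to 111) to 191 (187 to 195) tags per M and Pou5f1 from 94.9 (91.9 to 98.0) to 147 (144 to 151). For naive pluripotency the H3K4me3 median was 0.25 with 11 of 13 genes higher (random sets -0.03 to 0.17), at a summed width of 0.09 and tags per kb of 0.03. Tbx3 (chromosome 5, 119670534 to 119684724) stood at 314 (307 to 320) against 206 (201 to 212) and Klf5 at 252 (246 to 258) against 185 (180 to 190), while Dppa3 stood at 23.7 against 27.6. H3K4me1 of the naive list went the other way, with a median of -0.17 and 3 of 13 higher (random sets -0.06 to 0.37), a summed width of -0.02 and tags per kb of -0.14. The X-linked Nr0b1 went from 2.22 (1.77 to 2.76) to 1.17 (0.912 to 1.47) tags per M of it. Formative and primed genes had an H3K4me3 median of 0.22 with 10 of 13 higher (random sets -0.03 to 0.15), a summed width of 0.09 and tags per kb of 0.10; Otx2 stood at 70.4 (67.3 to 73.7) against 39.6.

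Primitive endoderm genes were lower here too, with an H3K4me3 median of -0.11 and 1 of 8 genes higher (random sets -0.05 to 0.19), at a summed width of -0.04 and tags per kb of -0.06. Gata6 stood at 64.2 (61.2 to 67.3) tags per M against 78.9 (75.5 to 82.5), over 6180 bp against 8182, and Lama1 at 49.5 against 54.6. For Hox genes the H3K4me3 median was -0.08 with 15 of 38 higher, below the random sets (-0.05 to 0.07), and the widths stood at -0.00. The limit given above for clustered Hox genes holds here too. Hoxa5, which carried Mll1, had 66.3 (63.2 to 69.5) against 70.3 (67.1 to 73.7). The germline list stood at -0.06 with 6 of 12 higher, and neuroectoderm at -0.02 with 6 of 14 higher, both inside the random sets. Among housekeeping genes the median was 0.14 with 12 of 15 higher, inside the random sets (-0.02 to 0.15), and the ribosomal gene Rplp0 stood out at 144 (139 to 148) against 62.5 (59.5 to 65.7).

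Few genes lost a mark after 4-OHT: 140 of 16163 (0.866%) for H3K4me1, 129 of 16083 (0.802%) for H3K4me2 and 170 of 15225 (1.12%) for H3K4me3, while 433, 203 and 163 gained it. With lists of equal number, 219 lost and 769 gained H3K4me1, while 170 lost and 121 gained H3K4me2, so that for H3K4me2 losses outnumbered gains. Among list genes, 0, 2 and 0 lost it and 5, 2 and 0 gained it. Jarid2, a subunit of the Polycomb repressor PRC2, and Acta2 lost H3K4me2, and the Polycomb count of 1 lay above the matched random sets (0). With an upper bound of 0, the loss of any 1 gene would lie above them. H3K4me1 was gained at Tbx5, Tex101, Rarb, Col3a1 and Gata1, and H3K4me2 at Hnf4a and Ywhaz. Genes named for lost H3K4me3 were Ift46, Npr2, Tasor2, Nin, Tbc1d5, Lrrfip1, Zpbp, Mrgbp, Ttc39c and Trim55, all of which kept an overlapping peak. Those named for gained H3K4me3 were Vapa, Mkrn1, Acp4, Zc2hc1c, Slc23a1, Klhl3, Cd80, Pgc, Ptpn22 and Fbxo33, each with an untreated peak under the new one. Gained H3K4me1 was named at Zfp59, the cyclin gene Ccnl1, Slc29a4, the heterochromatin protein gene Cbx3 and Nr5a1, among others, and gained H3K4me2 at Gp1ba, Pdgfa, Acsbg2, Orc1, a subunit of the replication origin complex, and Il1a, and at all of these an untreated peak already lay under the new one. Of the genes where the 4-OHT H3K4me3 peak overlapped none in untreated cells, chosen after their values were seen, Elobl had the highest score (chromosome 11, 88967381 to 88971398, 1224 tags), although its untreated H3K4me1 peak (88961748 to 88974157, 3460 tags) and H3K4me2 peak (88966296 to 88971533, 1617 tags) had no 4-OHT peak over them. Apol6 (chromosome 15, 77055716 to 77058398, 165 tags) and Gpx2, a glutathione peroxidase of the gut (chromosome 12, 76793823 to 76795926, 153 tags), were others.

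Among the named genes that lost H3K4me1 after 4-OHT, 3 had no overlapping peak: Zdbf2, an imprinted gene (peak on chromosome 1, 63197607 to 63220432, 3353 tags), Il34 (chromosome 8, 110802625 to 110811147, 760 tags) and Zfp982. The others were Siglecf, Rif1, Timd4, Rnase11, Tasor2, Akap6 and Mybphl. For H3K4me2 they were Jarid2 (chromosome 13, 44727709 to 44766685, 7707 tags) and Coil, the marker of Cajal bodies (chromosome 11, 88972310 to 88978769, 1167 tags), beside Ager, Nktr, Proca1, Mfsd4b5, Nrl, Trim30b, Golga7b and Aqp6. Wide peaks missing from a list are a limit here: of 9051 untreated H3K4me1 peaks of at least 5 kb, 257 (2.84%) had no 4-OHT H3K4me1 peak although 98.8% of those overlapped 4-OHT H3K4me2. At Jarid2 the 4-OHT H3K4me3 peak spanned 51204 bp (44728302 to 44779505) where the H3K4me2 list had none.

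Across the genome, 4-OHT left 9.35% (9.18 to 9.51) of H3K4me1, 6.44% (6.28 to 6.60) of H3K4me2 and 8.19% (7.96 to 8.43) of H3K4me3 peaks without an overlapping peak, and 16.7% (16.5 to 16.9), 18.2% (18.0 to 18.4) and 15.6% (15.3 to 15.9) of 4-OHT peaks were gained. At gene ends 2.14%, 1.45% and 1.73% were lost against 11.3%, 7.69% and 10.9% elsewhere. In the upper 50% of untreated scores, 0.917%, 0.036% and 0% were lost. H3K4me3 peaks of at least 10 kb numbered 314 against 87 in untreated cells and 95 after MM-401. Limiting lists to equal numbers gave gained shares of 16.4%, 11.9% and 9.66%.

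Chromosome X had a larger share of gained peaks than any autosome in 5 of 6 comparisons, most of all for H3K4me1. After 4-OHT, 870 of its 2774 H3K4me1 peaks were gained, or 31.4% (29.6 to 33.1), against 16.3% on the autosomes together and 13.9% to 18.4% on single ones. After MM-401 the share was 10.0% (8.52 to 11.7) against 3.24%, with single autosomes from 2.62% to 3.99%. Autosomal peaks of the same score and width had gained shares of 21.5% and 5.38%. The other marks were also above every autosome except for H3K4me3 after 4-OHT, at 11.6% (10.0 to 13.3) against 15.7%. H3K4me2 stood at 21.0% after 4-OHT and 4.53% after MM-401, where the highest autosomes had 19.9% and 3.58%, and H3K4me3 after MM-401 stood at 2.16% where the highest had 1.34%. This contrast was chosen after the values were seen. A larger gained share did not always go with more peaks on X. After MM-401, H3K4me1 peaks on X went from 2244 to 1469, and X lost 41.2% against 34.3% on the autosomes. After 4-OHT they went to 2774, and X lost 6.28% against 9.40%.

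**Figure D3:**
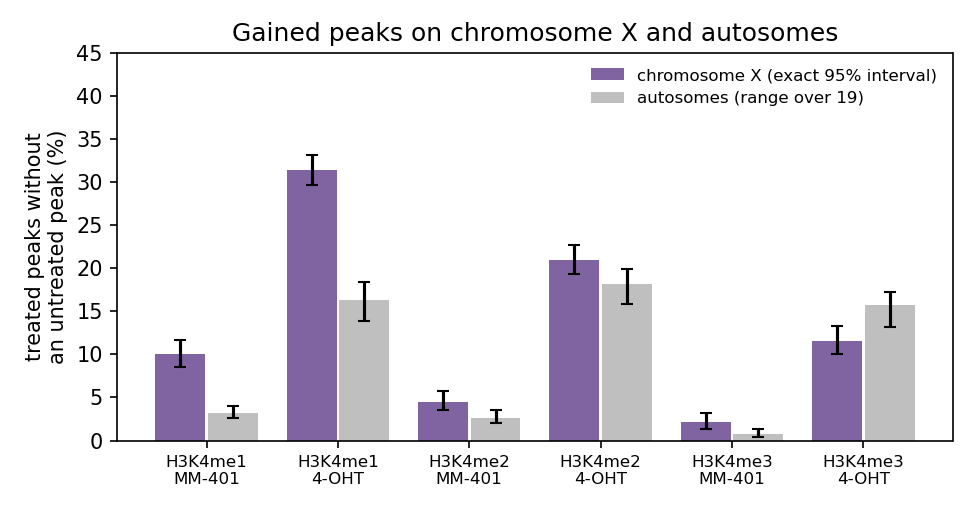
Share of treated peaks without an untreated peak (vertical axis, percent) on chromosome X with exact 95% intervals, beside the autosomes together with the range over the 19 autosomes, for each mark and treatment. For H3K4me1, X stands at 31.4% after 4-OHT and 10.0% after MM-401, above every autosome.

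Whether loss of methylation followed Mll1 binding was asked by setting peaks that overlapped Mll1 against others of the same score and width. Genes with Mll1 at an end rarely lost a mark: of 914 such genes with H3K4me3, 9 lost it after MM-401 and 3 after 4-OHT, of 921 with H3K4me1 8 and 2 did, and of 924 with H3K4me2 5 and 2 did. After MM-401, 7.33% (6.37 to 8.39) of Mll1-overlapping H3K4me1 peaks were lost against 10.6% of matched peaks, 6.32% (5.40 to 7.34) against 7.54% for H3K4me2, and 13.2% (11.7 to 14.8) against 14.7% for H3K4me3. After 4-OHT the shares were 2.41% (1.86 to 3.06) against 2.74%, 0.795% (0.486 to 1.22) against 1.04%, and 1.43% (0.947 to 2.08) against 2.05%. For H3K4me1 and H3K4me2 after MM-401 the interval lies below the matched share, and in the other 4 cases it includes it. At gene ends alone the differences for H3K4me1 and H3K4me3 after 4-OHT were 0.30 and 0.01 percentage points in place of -0.33 and -0.61. After MM-401 they were -1.69, -0.35 and -0.35 for H3K4me1, H3K4me2 and H3K4me3. Only the absence of a peak was counted here, so a lower level within a kept peak could not show.

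The last comparison asks whether MM-401 and 4-OHT affected the same regions. Genes that lost H3K4me3 under both treatments numbered 155, against 67.1 for losses independent within classes of score and width (7.78 without classes). For H3K4me1 they numbered 116 against 54.8 (9.59 without classes) and for H3K4me2 109 against 45.8 (5.02 without classes). At 132, 104 and 92 of these genes the untreated peak itself had no overlapping peak under either treatment. Named for H3K4me3 were the ciliary gene Ift46, the natriuretic peptide receptor gene Npr2, Nin, Tbc1d5, Gsdme, Prrxl1, Mfsd4a, Tex21, Shank3, a scaffold of synapses, and Rbp3, and at all 10 an overlapping peak stayed in at least 1 treatment, outside the 1 kb. For H3K4me1 the named genes included Siglecf, Timd4, Tasor2, Mybphl, Dhrs9 and Smyd1, and for H3K4me2 they were Proca1, Trim30b, Aqp6, Tspan8, Wfdc5, Olfr608, Cyp2a5, Fbxw13, Alpk2 and Slc4a5; 2 and 1 of the 10 named lacked an overlapping peak under both treatments, among them Dhrs9 and Alpk2. Among peaks, 9850, 5404 and 4201 were lost under both, against 7998, 4705 and 3818 for losses independent within classes of score and width. Part of the excess of genes and of peaks can come from the untreated list that both comparisons share. MM-401-gained peaks were also gained after 4-OHT in 65.3%, 67.8% and 64.7% of cases, and shuffled peaks in 2.23%, 1.78% and 0.813%. The shuffled shares do not cover the untreated list that both gains share: a region missed in that list counts in both.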

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

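Every test weighed in this part was chosen after the result was seen. The covered length of each mark moved in opposite directions under the 2 treatments, which is what flagged it. After MM-401 it differed from untreated cells by -23.8% for H3K4me1, -20.6% for H3K4me2 and -19.9% for H3K4me3. After 4-OHT it was higher by 16.5%, 15.0% and 14.6%. The difference between the treatments was not tested, because each group is 1 library. Depth differed in the same directions, at 60.3%, 49.5% and 51.2% of the untreated tags for MM-401 and 167%, 121% and 105% for 4-OHT. The covered length can thus not be told apart from depth, nor for MM-401 from the batch.

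The Mll1 list also held 5 peaks on the mitochondrial genome, flagged because they lie outside the nuclear peaks used elsewhere. They lay at 1 to 5255 (8110 tags), 5330 to 6444 (1377 tags), 9410 to 9512 (74 tags), 9778 to 9871 (50 tags) and 10990 to 15704 (7557 tags). The false discovery rate was 23.1% for the peak at 9410, 25% for that at 9778 and 0% for the others. The weak enrichment of this library limits them too, and whether they reflect Mll1 was not tested.

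More than 30% of untreated peaks had no MM-401 peak, and lower depth, another batch and loss of Mll1 activity were weighed. Of peaks whose untreated tags, scaled to the MM-401 depth, still reached the MM-401 median, 2.55%, 0.561% and 0.123% were missing for H3K4me1, H3K4me2 and H3K4me3, against 0.983%, 0.0843% and 0.0111% by the same measure in the deeper 4-OHT libraries. A limit of 1%, set after these values were seen and passed by H3K4me1 alone, was dropped because depth gives no exact limit, so depth stays open, and the 82.6% missing among weaker H3K4me3 peaks could equally come from a loss of the mark there. Action of the inhibitor where Mll1 was bound could give more missing peaks there. The differences from matched peaks were -3.29, -1.23 and -1.46 percentage points for H3K4me1, H3K4me2 and H3K4me3, and -1.69, -0.35 and -0.35 at gene ends alone. More missing peaks at Mll1 peaks were thus not seen, although for H3K4me3 the interval reaches the matched share. Only the absence of a peak was counted. A lower level within a kept peak could not show, so action of the inhibitor at Mll1 peaks stays open. Batch cannot be told apart from MM-401, since 0 libraries of another condition were in its batch, and an indirect effect of the inhibitor was not tested.

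Gained H3K4me1 peaks were more frequent on chromosome X than on any autosome under both treatments, with smaller excesses for H3K4me2 and for H3K4me3 after MM-401, and weaker peaks or more copies of X could give this. Against autosomal peaks of the same score and width classes, X was still 4.63 percentage points higher after MM-401 and 9.82 after 4-OHT. Matching had raised the autosomal share from 3.24% to 5.38% after MM-401 and from 16.3% to 21.5% after 4-OHT. Weaker peaks may thus give part of the excess. Strength can also differ within a class, so the matching cannot decide whether they give all of it. More copies of X in the 4-OHT cells should raise every mark, but the tags of kept H3K4me3 peaks on X over those on autosomes stood at a ratio of 1.01, which argues against it. A change of methylation on X that follows Mll1, or a shared feature of the untreated lists that both comparisons use, stays open as a hypothesis and was not tested.

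H3K4me3 peaks at core pluripotency genes were wider after 4-OHT, and a deeper or more sensitive library, joining of neighbouring peaks and loss of Mll1 activity were weighed. With peaks under 1 kb apart joined in every library, the median log2 width ratio was 0.26, with 14 of 14 genes still wider. It lay inside the range of random genes matched on joined width alone, so joining of neighbouring peaks by the caller may account for part of the excess. A deeper or more sensitive library stays open, since it could itself join such peaks and the list lay at the 95.7th percentile of random genes after joining. Loss of Mll1 activity could not be decided, since the median ratio was 0.0085 after MM-401, and an inhibitor acting to another extent need not give the same.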

How the results depend on the processing

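Every alternative set before the data gave a value, with the inferred start standing for the annotated start; those marked as added, and no others here, were chosen after seeing the data. Of 218 alternatives to 54 results, 104 stayed within the interval of the value (or within 1.5 times a count) and 114 moved. The cause was not tested. A change of direction was scored only for differences at Mll1-overlapping peaks whose interval excluded 0, and for ratios of peaks lost in both treatments. Among these it was seen in 0 cases, and the other results could not be scored so. The balance of genes losing and gaining a mark did turn with lists of equal number, for H3K4me1 after MM-401 (539 lost, 629 gained) and for H3K4me2 after 4-OHT (170 lost, 121 gained). It turned for H3K4me3 after 4-OHT in the upper 50% of each list by score (127 lost, 182 gained, against 170 and 163 as deposited) and was even with a 2.5 kb window (160 and 160). With lists of equal number the gained share of H3K4me3 peaks after MM-401, 11.2%, also passed the lost share, 10.6%. Values are for H3K4me1, H3K4me2 and H3K4me3 in that order unless a mark is named, shares are percent, and differences are percentage points. In the lowest of 10 score classes 93.3% of H3K4me3 peaks had no MM-401 peak, and whether depth or treatment removed them was not decided.

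With 50% of the peak covered, MM-401 lost shares were 36.6, 34.6 and 38.7 and gained shares 3.95, 3.09 and 1.44. For 4-OHT, lost shares were 9.75 and 6.73 for H3K4me1 and H3K4me2, gained shares were 19.2, 19.5 and 17.1, and 69.8 of Mll1 peaks had H3K4me1. With peaks within 1 kb counted as shared, MM-401 lost shares were 29.1, 30.3 and 36.0, gained 2.56, 2.20 and 0.711, and 4-OHT lost 7.48, 5.57 and 7.46, gained 13.6, 14.9 and 13.5. Mll1 peaks then had the marks in 80.1, 75.0 and 58.5, and Mll1-overlapping minus matched lost shares were -5.45 and -2.27 for H3K4me1 and H3K4me2 after MM-401, and -0.98 and -1.24 for H3K4me1 and H3K4me3 after 4-OHT.

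In the upper 50% of each list by score, MM-401 lost shares were 35.5 and 32.7 for H3K4me1 and H3K4me2 and gained shares 5.85, 1.5 and 0.062. For 4-OHT, lost shares were 11.5, 4.94 and 5.15 and gained 17.4, 16.4 and 11.8. Mll1 peaks had the marks in 63.0, 64.9 and 45.2, the difference for H3K4me2 was -2.30 after MM-401 and -0.56 after 4-OHT, and 5449, 2121 and 1353 peaks were lost in both. Genes losing H3K4me1 numbered 2684 after MM-401 and 365 after 4-OHT, genes gaining it 367 and 1315, and genes losing H3K4me3 after MM-401 1205. With lists of equal number, MM-401 lost shares were 16.3, 13.1 and 10.6 and gained 13.4, 12.8 and 11.2. For 4-OHT, lost shares were 8.82 and 8.64 for H3K4me2 and H3K4me3 and gained 16.4, 11.9 and 9.66. Peaks lost in both numbered 4607, 3140 and 1487. Genes losing the mark after MM-401 numbered 539, 246 and 227, genes gaining it 629, 139 and 161. After 4-OHT 219 genes lost H3K4me1, 769 gained it and 121 gained H3K4me2.

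With peaks under 1 kb apart merged, MM-401 lost shares were 32.7 and 37.5 and gained 2.5 and 0.758 for H3K4me2 and H3K4me3, and 4-OHT gained 15.9, 15.8 and 13.5. Without matching, Mll1-overlapping minus other lost shares were -27.7, -28.3 and -25.9 after MM-401 and -7.10, -5.81 and -7.01 after 4-OHT. At gene ends only the MM-401 H3K4me1 difference was -1.69, and away from them the 4-OHT H3K4me3 difference was -1.34.

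At the inferred start alone, 79 genes gained H3K4me1 after MM-401, and after 4-OHT 49 lost and 216 gained it; 204 lost and 3 gained H3K4me2 after MM-401, and 13 lost and 28 gained it after 4-OHT. Where the treated peak itself had to lack an untreated peak (added), 15 genes gained H3K4me2 and 5 gained H3K4me3 after MM-401. With a 2.5 kb window, 32.8 of Mll1 peaks were at gene ends, and of mark peaks 26.6, 24.7 and 34.1 in untreated cells, 32.0, 31.3 and 47.5 after MM-401 and 26.2, 23.4 and 32.7 after 4-OHT. Core pluripotency H3K4me3 after 4-OHT had a median log2 ratio of 0.48 by the nearest peak and 0.48 by summed width (added). The number of gene lists with a count of lost genes outside the random sets, of 126, was 1 in each setting but not the same list: Polycomb subunits for H3K4me2 after 4-OHT with matching or a 2.5 kb window, and blood and endothelium for H3K4me1 after MM-401 without matching.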

Other observations

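No explanation is offered in this part; the contrasts by single genes were chosen after their values were seen. After 4-OHT, genes of the H3K4 methylation machinery had a median log2 ratio of H3K4me1 tags of 0.43 with 17 of 17 genes higher, above the random sets (0.00 to 0.40). This held for the tag sum alone: cover within 5 kb, the measure chosen first, stood at 0.12 (random sets 0.04 to 0.26), summed width at 0.41 and tags per kb at -0.03, all inside. Setd1a, the catalytic subunit of another H3K4 methyltransferase complex, stood at 30.0 tags per M against 7.95 and Kmt2b, the closest relative of Mll1, at 90.4 against 30.2. Imprinted genes had a median of 0.67 with 8 of 9 higher (random sets -0.00 to 0.54) and a summed width of 0.61 (0.06 to 0.59), but cover stood at 0.12 (0.03 to 0.38) and tags per kb at 0.02, both inside. Impact stood at 6.28 (5.67 to 6.94) against 2.58 (2.08 to 3.15) and Peg10 at 8.86 (8.13 to 9.63) against 4.56 (3.89 to 5.30). Polycomb subunits, which silence developmental genes, had wider H3K4me2 after 4-OHT, with a median summed width of 0.32 and 12 of 13 genes wider (random sets 0.01 to 0.31) but cover of 0.07 inside them (-0.01 to 0.11), and the Ezh2 peak spanned 15389 bp against 6559.

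After MM-401, H3K4me1 was also higher for Wnt signalling, with a median tag ratio of 0.38 and 12 of 13 genes higher (random sets -0.25 to 0.26), tags per kb of 0.37 (0.07 to 0.32), and a cover of -0.01 and summed width of -0.04 that lay inside. FGF and MAPK signalling stood at 0.40 with 7 of 10 higher (random sets -0.24 to 0.28), and cover at 0.03 was above its sets too (-0.30 to 0.01), while tags per kb of 0.21 (0.05 to 0.31) and a summed width of -0.03 lay inside. H3K4me2 of the Hox cofactors and leukemia targets of MLL1 fusions stood at 0.38 with 11 of 11 higher (random sets 0.06 to 0.27), with Meis2 at 119 tags per M against 80.8. Adhesion and epithelial-mesenchymal transition stood at 0.28 with 13 of 14 higher (0.08 to 0.26), and fibroblast genes at -0.06 with 2 of 7 higher (-0.01 to 0.33). By cover the first 2 of these lay inside the random sets, at 0.02 and -0.03, and fibroblast genes below them at -0.32 (-0.27 to 0.07). H3K4me2 of primitive streak and mesoderm genes stood at 0.25 and that of blood and endothelium at 0.29, both inside the random sets. Of the 2-cell-stage genes, only Duxf3 and Eif1a had a peak of H3K4me2 or H3K4me3. Over all lists, marks and treatments, 35 of 118 medians of tags lay outside the central 95% of the random sets. By cover within 5 kb, the measure chosen first, 19 did, by peak width 20, by summed width 24 and by tags per kb 25. Independent medians with exact random sets would give 5.9. The medians share lists and untreated libraries, and medians without an effect were not simulated, so 5.9 does not measure an excess.

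Among the H3K4me3 peaks that were most widened after 4-OHT were those at Jarid2, from 11.3 to 51.2 kb, at the DNA demethylation gene Tet1 (chromosome 10, 62869119 to 62909558), from 13.0 to 40.4 kb, at Actn4, from 5.78 to 29.9 kb, at Trim71, from 22.8 to 42.5 kb, and at the corepressor gene Ctbp2, from 17 to 31.7 kb. After MM-401 the same peaks were 10.5, 19.3, 9.42, 22.6 and 17.6 kb wide. The lost share of untreated H3K4me1 peaks after 4-OHT was 36.8% under 1 kb, 10.4% at 1 to 2 kb, 0.882% at 2 to 5 kb, 1.82% at 5 to 10 kb, 5.41% at 10 to 20 kb and 14.8% from 20 kb. Most lost peaks were narrow, and 252 of the 257 lost peaks of at least 5 kb had an MM-401 H3K4me1 peak.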
